A study of Mus musculus with 6 samples.

How the data were processed

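The data are 6 Affymetrix Mouse Gene 1.0 arrays of bone marrow cells of C57B/6 mice, which per the labels' protocols were cultured for 6 days with 20 ng/ml recombinant GM-CSF and received no further treatment. Total RNA was extracted from each sample and 6 ug of it was biotin-labelled, per the labels. The cell type label of each sample gives its population, dendritic (n = 3) or macrophage (n = 3), and the sample titles give replicate numbers 1 to 3 in each. How the populations were separated from the culture, and whether the replicates come from separate mice or cultures, is not given in the sources used here. P-values therefore measure only the spread between these samples, which may be technical.

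The deposited values are on a log2 scale, 1 per probe set and array for 35556 probe sets, and the authors made them with RMA and R 3.0.2, per the submitters' processing notes. RMA corrects the background, normalizes arrays by quantiles and summarizes the probes of a probe set. The set of arrays on which it was run, the probe set definition and any filter are not given in the sources used here. The values reach from 1.29 to 13.4, and the median of all probe sets on an array lay between 4.79 and 4.96. There are no detection calls, and no genome build is named, so no coordinates are given. RMA values compress differences of dim probe sets, so a fold against a population near the background is a value on this scale and not a measure of transcript number.

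Probe sets were named through the platform's gene table. Exactly 1 gene symbol was held by 21789 probe sets, several symbols by 1621, and 12146 were not in the table and stay unnamed. Symbols were updated through the Entrez identifier in a RefSeq gene table of the assembly GRCm38.p6, in which 21698 of the named probe sets were found and 0 symbols changed. Where a gene had several probe sets (999 genes), the probe set with the highest mean over all arrays was used, which left 19938 genes. The 13767 probe sets without a single symbol were tested only in the alternative that tests all probe sets, where 846 of them were called.

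The test was limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3 on the deposited log2 values of all 6 arrays, with the population as the only term, no filter on level and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. The larger differences were counted at a log2 difference of at least 1 (2-fold) and of at least 3 (8-fold). Gene lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over 39 lists. The version with an estimated correlation also tests on the 4 residual degrees of freedom of the fit. A call lost there can thus reflect the few arrays as well as correlation between genes. Of 907 list members 842 were measured by a probe set with a single symbol, and the others were not analysed here. Files were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

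The comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The genes named are the 10 with the largest difference in each direction among called genes whose populations do not overlap, leaving out predicted genes, small RNA genes and olfactory and vomeronasal receptors, a set of focal genes of dendritic cells and macrophages, and for each list up to 2 called members with the largest difference in each direction. A few others are named because a count was small, or as examples, and were chosen after their values were seen. The rule gave 126 genes.

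The replicate numbers in the titles may pair the samples. The deviations of same-numbered arrays from their population means correlated at 0.385 (number 1), 0.147 (number 2) and 0.272 (number 3), all over 0.1, and by this the numbers were taken to pair the samples. Dendritic replicate 2 correlated slightly more with macrophage replicate 3 (0.155), and dendritic replicate 3 with macrophage replicate 2 also passed 0.1 (0.128). The deviations in a population sum to 0, so a shared deviation of number 1 alone raises the correlations among numbers 2 and 3. The pairing thus rests mostly on number 1, and number 2 does not stand apart from the unmatched pairs. The labels do not say what a number marks. A fit with the number as a block was therefore set beside the main one.

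On simulated data with the spread of these 19938 genes, the dendritic minus macrophage test recovered 3 of 67 genes changed by a log2 difference of 0.5, 65 of 67 changed by 1 and 66 of 66 changed by 2, with 8 false calls among 142. Of 200 random lists in the same simulation 5 had a camera p under 0.05. The simulated genes were independent of each other, so this does not measure how often camera calls a list of correlated genes wrongly. Differences near 0.5 are thus mostly missed at this spread when few genes differ.

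The alternatives were quantile normalization applied again, centring on the median or the 75th percentile of each array, leaving out genes under the 30th percentile or the median of mean level, the mean over the probe sets of a gene, an intensity trend with robust eBayes, array weights, the replicate block, each array left out, all probe sets tested, an adjusted p of 0.01, treat against a log2 difference of 1, and camera on ranks or with an estimated correlation. Leaving out replicate 1 of both populations was added after the data were seen.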

Results

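Gene expression was measured on 6 Affymetrix Mouse Gene 1.0 arrays. Bone marrow cells of C57B/6 mice had been cultured for 6 days with 20 ng/ml GM-CSF, the cytokine granulocyte-macrophage colony-stimulating factor, which drives the growth and differentiation of myeloid cells. The labels divide the culture into a dendritic population (3 arrays) and a macrophage population (3 arrays), both unstimulated, and the comparison asked how the expression profiles of these populations differ. The labels used here do not name the surface markers by which the populations were separated. If Itgam (CD11b), Itgax (CD11c), H2-Ab1 (MHC class II) or another gene below was used for that, its difference is part of the separation and not an independent result. Values are the deposited log2 RMA values, and every difference is the dendritic mean minus the macrophage mean on the log2 scale, ± SE, with n = 3 arrays per population. The number of arrays limits the precision.

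The populations differed widely. Of 19938 genes tested with limma, 4312 (21.6%) passed a Benjamini-Hochberg adjusted p of 0.05, of which 1990 were higher and 2322 lower in the dendritic population. A difference of at least 2-fold was reached by 2051 of these (891 higher, 1160 lower), and a difference of at least 8-fold by 259 (87 higher, 172 lower). When the size itself was tested against a log2 difference of 1 (treat), 838 genes passed (350 higher, 488 lower). The values of the populations did not overlap for 6781 genes (34.0%), where chance gives 10%. Across genes, which are not independent replicates, arrays of a population correlated at r = 0.980 to 0.993 and arrays of different populations at 0.903 to 0.923. The first principal component, which separated the populations, held 78.9% of the variance.

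The gene with the largest difference upward in the dendritic population was Fscn1 (probe set 10527158), which encodes the actin-bundling protein fascin. It had a log2 value of 11.44 ± 0.11 (SD, n = 3) in the dendritic arrays, 6.45 ± 0.12 (SE) above the macrophage arrays, an 87.2-fold difference (limma adjusted p = 4.22e-08). Stat4 (probe set 10346168), a transcription factor of interleukin-12 signalling, followed at 6.43 ± 0.24, with Ceacam15 at 6.38 ± 0.14 and the serine protease inhibitors Serpinb6b at 6.30 ± 0.16 and Serpinb9 at 5.53 ± 0.27. The interleukin-2 receptor alpha chain Il2ra (5.39 ± 0.20), the receptor-activity-modifying protein Ramp3 (5.31 ± 0.17) and the lymph node homing receptor Ccr7 (5.30 ± 0.26) were also among the 10 largest. So were the actin-severing protein Scin (5.27 ± 0.32) and Il12b (5.19 ± 0.21), the p40 subunit shared by interleukins 12 and 23. Adjusted p for these 10 genes was at most 5.80e-06.

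In the other direction the largest difference was that of the C-type lectin Mgl2 (probe set 10377774), 3.63 ± 0.59 (SD, n = 3) in the dendritic and 10.07 ± 0.63 in the macrophage arrays, or 86.6-fold lower (limma adjusted p = 3.29e-06). The monocyte chemokine receptor Ccr2 (probe set 10590631) differed by -6.34 ± 0.15, the acute-phase gene Saa3 by -6.25 ± 0.27, the TGF-beta-induced matrix protein Tgfbi by -6.18 ± 0.25 and the C-type lectin Clec4d by -6.03 ± 0.19. Platelet factor 4 (Pf4, -5.91 ± 0.29), the scavenger receptor Msr1 (-5.83 ± 0.20), the M-CSF receptor Csf1r (-5.76 ± 0.15) and the collagenase Mmp8 (-5.63 ± 0.41) were also among the 10 largest. Klk1b1 (-5.77 ± 0.42) belongs to a family of near-identical kallikrein genes, so its probe set may take signal from its relatives and the gene is uncertain. For these 20 genes the dimmer population's mean lay between 3.14 and 6.15, where the median of all probe sets on an array was 4.79 to 4.96. The table holds no detection calls, so whether the gene was expressed at all in that population is not known.

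**Figure D1:**
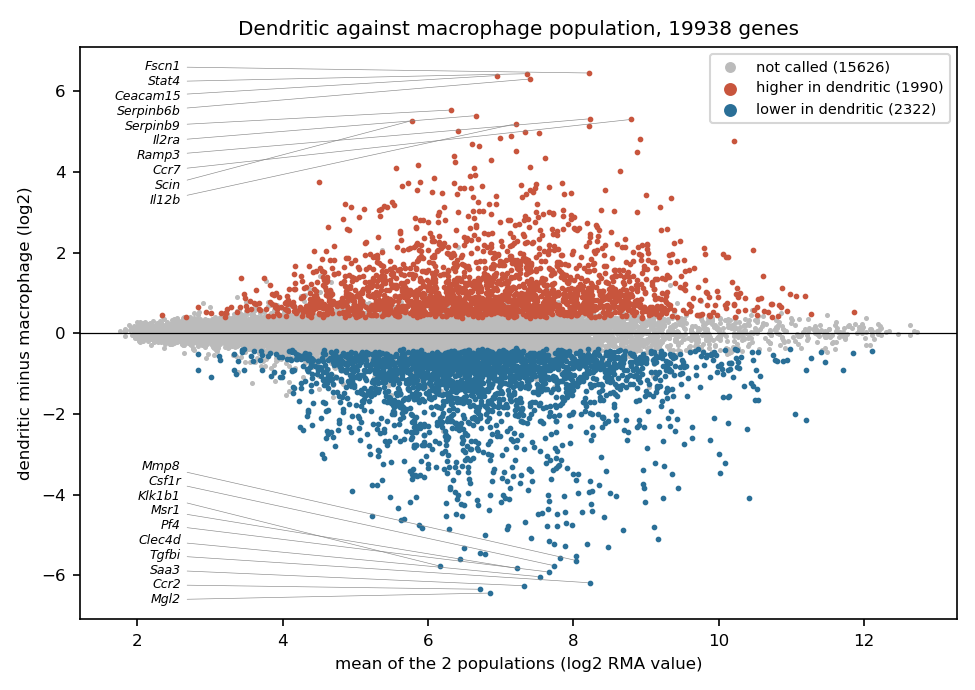
Difference between the populations (vertical axis, log2, dendritic minus macrophage) against the mean of the populations (horizontal axis, log2 RMA value) for each of 19938 genes. Red points mark the 1990 genes called higher in the dendritic population and blue points the 2322 called lower at a limma adjusted p under 0.05, grey points the genes not called, and the 10 genes with the largest difference in each direction are named.

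Genes of dendritic cell identity were mostly higher in the dendritic population. Of 37 measured members of the DC identity list, 23 were higher, 3 were lower and 11 did not pass (25 higher and 6 lower when adjusted over the list alone). The members higher included Ccr7, Scin, the growth factor receptor Flt3 (probe set 10535780, 4.70 ± 0.14, adjusted p = 2.45e-07), the MHC class II chain H2-Eb2 (3.59 ± 0.20), the peptidase Dpp4 (3.21 ± 0.31) and Zbtb46 (probe set 10490682, 1.82 ± 0.15, adjusted p = 3.06e-05), a transcription factor of the conventional dendritic lineage. The 3 lower members were the kynurenine pathway enzyme Kmo (-2.28 ± 0.21), the cytoskeletal adaptor Pstpip1 (-1.77 ± 0.12) and the aminopeptidase Anpep (-1.32), the last named after its values were seen. With the replicate number as a block 6 members were lower, and 6 also without macrophage replicate 1. The list as a whole stood higher than other genes (camera adjusted p = 7.83e-11), and this call was lost with an estimated correlation (adjusted p = 0.0622).

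The transcription factors of dendritic cells moved the same way. Of 20 measured, 16 were higher and 3 lower, as also when adjusted over the list alone (camera adjusted p = 6.32e-10, and 0.0317 with an estimated correlation). Besides Stat4, the largest difference was that of the Ets factor Spib (4.28 ± 0.21), and Irf8 was higher by 2.23 ± 0.19 (adjusted p = 4.16e-05). Irf4 was higher by 0.86 ± 0.24 (adjusted p = 0.0315). Its call was lost without dendritic replicate 2 (adjusted p = 0.106), without dendritic replicate 3 (0.0885) and after quantile normalization was applied again (0.0537), within a range of 0.00699 to 0.106 over the alternatives. The 3 lower members were Zeb2 (-2.93 ± 0.26), Ikzf1 (-0.76, named after its values were seen) and Klf4 (-1.25 ± 0.36). The call of Klf4 was lost without dendritic replicate 2, macrophage replicate 2 or macrophage replicate 3 (range of adjusted p over the alternatives, 0.00862 to 0.120).

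Genes of macrophage identity were lower in the dendritic population almost throughout. None of 39 measured members was higher and 35 were lower, the same counts as when adjusted over the list alone (camera adjusted p = 1.88e-31, and 0.0356 with an estimated correlation). Csf1r (probe set 10456071) fell from 10.62 in the macrophage to 4.86 in the dendritic arrays, a 54.1-fold difference (adjusted p = 9.59e-08). The lipopolysaccharide co-receptor Cd14 differed by -4.77 ± 0.20, the high-affinity IgG receptor Fcgr1 by -4.24 ± 0.15, the apoptotic cell receptor Mertk by -4.20 ± 0.15 and the adhesion receptor Adgre1 by -4.00 ± 0.12. Among 19 macrophage transcription factors, 13 were lower and 1 higher (14 and 2 when adjusted over the list alone; camera adjusted p = 2.35e-08, and 0.0317 with an estimated correlation). The largest differences were those of Tfec (-4.77 ± 0.19) and Bhlhe41 (-2.98 ± 0.19), while Bhlhe40 was the higher member (1.77 ± 0.19). The higher members numbered 2 with the replicate number as a block and without dendritic replicate 2.

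Markers that the 2 cell types share, or that are often used to separate them, did not all follow the population names. The integrin chains Itgam (-5.23 ± 0.20, adjusted p = 5.54e-07) and Itgax (-2.52 ± 0.44, adjusted p = 0.00285) and the inhibitory receptor Sirpa (-2.42 ± 0.14) were lower in the dendritic population. Of the GM-CSF receptor chains, Csf2ra was lower (-1.82 ± 0.18, adjusted p = 0.000103) and Csf2rb differed by 0.29 ± 0.15 (adjusted p = 0.248, not called). The fractalkine receptor Cx3cr1 differed by -1.39 ± 0.46 and was not called (adjusted p = 0.0622). It was called with the replicate number as a block (adjusted p = 0.0330). It was also called without macrophage replicate 1 (-0.76, adjusted p = 0.0280), without macrophage replicate 2 (0.0386) and without macrophage replicate 3 (0.0487), within a range of 0.0280 to 0.178 over the alternatives. Centring on the 75th percentile (limma adjusted p = 0.0449) and leaving out genes under the 30th percentile (0.0491) or the median of level (0.0473) gave a call too. In all, Cx3cr1 was called in 8 of 16 alternatives. Macrophage replicate 1 held a Cx3cr1 value of 8.46 against 6.57 in macrophage replicate 2.

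**Figure D2:**
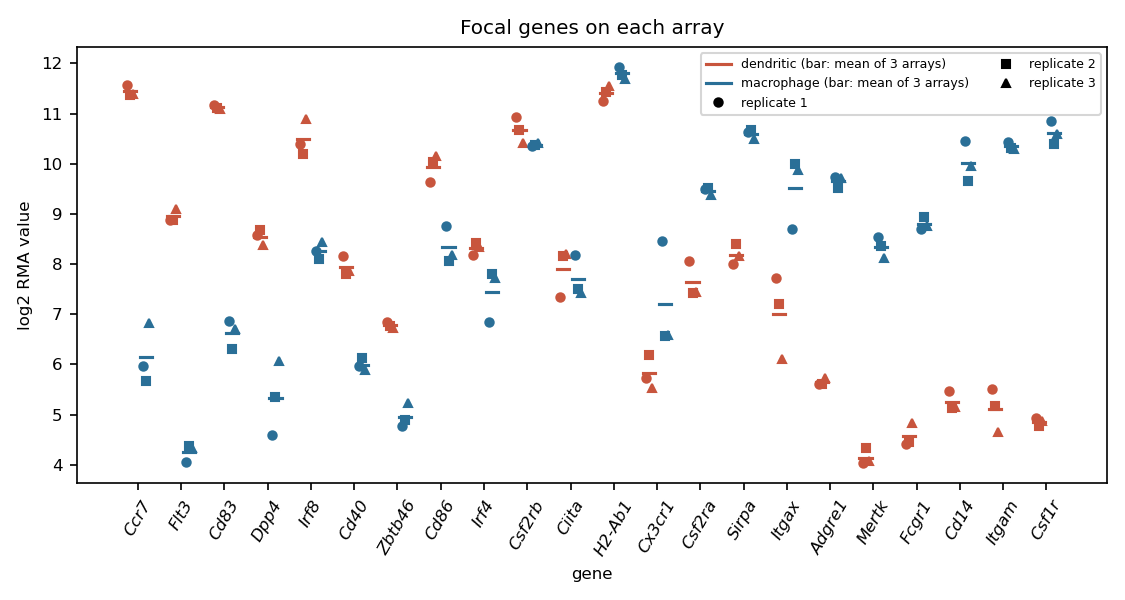
Log2 RMA value (vertical axis) of each focal gene (horizontal axis) on the 3 dendritic arrays (red) and the 3 macrophage arrays (blue), with the marker shape giving the replicate number and the bar the mean of 3 arrays. From left to right the difference runs from Ccr7, 5.30 higher in the dendritic population, to Csf1r, with -5.76, and for Csf2rb, Ciita, H2-Ab1 and Cx3cr1 it did not pass the limma test.

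Genes of dendritic cell maturation and migration formed the list with the highest median. Of 28 measured members 24 were higher and 1 was lower, as also when adjusted over the list alone, with a median log2 difference of 2.999 (camera adjusted p = 5.01e-23, and 0.0322 with an estimated correlation). Fscn1, Stat4, Serpinb6b, Serpinb9 and Ccr7 belong to this list, which shares 2 members with the DC identity list and 4 with the NF-kB list. The lower member, the cystatin Cst7 (-0.79 ± 0.22, adjusted p = 0.0338), lost its call when any array except macrophage replicate 1 was left out, while 2 members were lower without that array. Centring on the 75th percentile also lost the Cst7 call (limma adjusted p = 0.0654). The adjusted p of Cst7 ranged from 0.00290 to 0.115 over the alternatives. Of the NF-kB pathway and its targets, 18 of 22 were higher and 1 was lower (20 and 1 when adjusted over the list alone), led by the kinase Map3k14 (3.19 ± 0.14) and the subunit Relb (3.005 ± 0.14), both of the non-canonical branch. The kinase Ikbke was the lower member (-1.90 ± 0.17). The NF-kB list was called (camera adjusted p = 1.31e-14), but not with an estimated correlation (adjusted p = 0.102).

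Costimulatory and checkpoint ligands were higher too. Of 16 measured, 13 were higher and 1 was lower, as also when adjusted over the list alone (camera adjusted p = 7.83e-11, and 0.0317 with an estimated correlation). Cd83 (probe set 10404840) differed by 4.50 ± 0.16 (adjusted p = 4.10e-07), the OX40 ligand Tnfsf4 by 4.08 ± 0.36, Cd40 by 1.95 ± 0.14 and Cd86 by 1.61 ± 0.21. The lower member, the lipid-presenting molecule Cd1d1 (-0.78 ± 0.22, adjusted p = 0.0368), lost its call when any array except dendritic replicate 2 was left out (range of adjusted p over the alternatives, 0.00690 to 0.135). That call was also lost after quantile normalization was applied again (limma adjusted p = 0.0617) and with 75th percentile centring (0.0622).

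Antigen presentation genes did not move as a block. In the MHC class II list 2 of 10 measured members were higher and 2 lower (2 and 3 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.691). Its median was -0.13 and its mean 0.30, so the direction depends on the summary. H2-Eb2 and H2-Oa (1.93 ± 0.27) were higher, and the peptide-loading chain H2-DMa (-1.06 ± 0.25) and the protease Ctss (-0.72 ± 0.13) were lower. The classical chain H2-Ab1 (probe set 10444291) was bright in both populations, at 11.41 ± 0.15 (SD, n = 3) in dendritic and 11.80 ± 0.12 in macrophage arrays, a difference of -0.39 that did not pass (adjusted p = 0.0745; 0.0126 to 0.246 over the alternatives). The class II transactivator Ciita differed by 0.19 ± 0.27 (adjusted p = 0.754), with a 95% interval from -0.42 to 0.81. Without replicate 1 of both populations, a setting chosen after seeing the data, Ciita differed by 0.71 (adjusted p = 0.00399; 0.00399 to 0.971 over the alternatives). Of the MHC class I pathway 6 of 13 were higher and 1 lower, as also when adjusted over the list alone, with Tapbpl (1.79 ± 0.17) and the peptide transporter Tap1 (1.42 ± 0.28) the largest. That list was called (camera adjusted p = 0.00570), but not with an estimated correlation (adjusted p = 0.102). The lower member, the chaperone Calr (-0.47 ± 0.14, adjusted p = 0.0452), lost its call when any array except dendritic replicate 3 was left out (0.0202 to 0.162 over the alternatives). Calr also lost its call after quantile normalization was applied again (limma adjusted p = 0.0818), with 75th percentile centring (0.108) and with array weights (0.0504).

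Receptors for uptake and microbial sensing were lower in the dendritic population. Of 25 Fc, complement and scavenger receptor genes, none was higher and 21 were lower (23 when adjusted over the list alone), with a median of -3.82 (camera adjusted p = 5.01e-23, and 0.0322 with an estimated correlation). Msr1 and the complement component C1qb (-5.58 ± 0.23) led this list. Of 28 pattern recognition receptors 19 were lower and 3 higher (20 and 3 when adjusted over the list alone), with Clec4d and Clec4n (-5.29 ± 0.20) the lowest, and Tlr12 (1.65 ± 0.32) and Nod2 (0.64 ± 0.14) among those higher. The receptor list was called (camera adjusted p = 7.83e-11), but not with an estimated correlation (adjusted p = 0.139). Of 24 efferocytosis and phagocytosis genes 12 were lower, led by Cd300ld (-4.25 ± 0.22) and Mertk, and 1 was higher, the engulfment adaptor Elmo1 (0.91 ± 0.20). When adjusted over the list alone these counts were 13 and 3. With the replicate number as a block 3 were higher, and 2 without dendritic replicate 2 or without macrophage replicate 1. The call of this list (camera adjusted p = 1.19e-05) was lost with an estimated correlation (adjusted p = 0.106).

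Lysosomal genes were lower with few exceptions. Of 42 measured, 37 were lower (38 when adjusted over the list alone) and none was higher, with a median of -1.30 (camera adjusted p = 7.60e-26, and 0.0317 with an estimated correlation). The proton pump subunit Atp6v0d2 (-5.28 ± 0.31) and the protease Ctsl (-3.93 ± 0.17) had the largest differences. Genes of lipid uptake and efflux were lower in 13 of 19 cases and higher in 1, as also when adjusted over the list alone, with Msr1 and the phospholipid transfer protein Pltp (-4.16 ± 0.49) lowest. The list call (camera adjusted p = 4.84e-08) was lost with an estimated correlation (adjusted p = 0.0622). The higher member, the ubiquitin ligase Mylip (1.06 ± 0.26, adjusted p = 0.0180), lost its call without dendritic replicate 1, dendritic replicate 3, macrophage replicate 2 or macrophage replicate 3 (0.000831 to 0.0682 over the alternatives). In the lipid list 2 members were higher with the replicate number as a block and without macrophage replicate 1. Matrix proteases and remodelling genes were lower in 16 of 21 cases and higher in 3, as also when adjusted over the list alone. Mmp8 and the macrophage elastase Mmp12 (-4.80 ± 0.37) were lower, and Adam19 (2.56 ± 0.17) and Timp3 (2.25 ± 0.17) higher. This call (camera adjusted p = 1.63e-07) was lost with an estimated correlation (adjusted p = 0.0611).

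Metabolic lists were lower in the dendritic population. Of 16 glycolysis genes 13 were lower and 1 higher (14 and 2 when adjusted over the list alone), with a median of -1.06. Aldoc (-3.47 ± 0.17) and the hexokinase Hk2 (-2.27 ± 0.20) were the lowest, and Pfkfb3 (2.34 ± 0.35), which makes the activator of phosphofructokinase, was the higher member. The list was called (camera adjusted p = 3.78e-07), but not with an estimated correlation (adjusted p = 0.162). Of 33 oxidative phosphorylation genes 18 were lower and none was higher (19 and 1 when adjusted over the list alone), with a median of -0.45 and the largest differences in Sdhb (-1.20 ± 0.15) and Ndufs1 (-1.02 ± 0.16). Without dendritic replicate 2 the lower members numbered 11 and without macrophage replicate 2 they numbered 9. With the replicate number as a block, and without dendritic replicate 1, 1 member was higher. This list was called (camera adjusted p = 1.91e-07), but not with an estimated correlation (adjusted p = 0.309). Of 19 cholesterol biosynthesis genes 8 were lower and 2 higher (9 and 2 when adjusted over the list alone; camera adjusted p = 0.0118, and 0.631 with an estimated correlation). Msmo1 (-1.79 ± 0.25) and Dhcr7 (-1.56 ± 0.27) were the lowest, and Idi1 (1.74 ± 0.36) and Pmvk (1.44 ± 0.35) were higher. Pmvk lost its call without dendritic replicate 3 (adjusted p = 0.0653; 0.00540 to 0.0653 over the alternatives), which left 1 higher member. Lower members numbered 5 without dendritic replicate 1 or macrophage replicate 2, and 4 without dendritic replicate 2 or macrophage replicate 3. The cholesterol call was lost without macrophage replicate 2 (adjusted p = 0.0642), with genes under the median level left out (0.0869) and with an estimated correlation, within a range of 7.17e-06 to 0.631 over the alternatives. In macrophage replicate 1 the median of this list was 7.05, against 8.16 and 8.23 on the other macrophage arrays and 6.87 to 7.41 on the dendritic arrays.

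Mitotic genes were lower in the dendritic population, to an extent that depended on the arrays used. Of 29 genes of G2 and M phase 10 were lower and none was higher (19 lower when adjusted over the list alone), among them the cyclin Ccnb2 (-2.22 ± 0.52, adjusted p = 0.0143) and the proliferation marker Mki67 (probe set 10568714, -2.15 ± 0.32, adjusted p = 0.00122). The median of the list was 6.28 and 6.25 in macrophage replicates 2 and 3 but 4.77 in macrophage replicate 1, which lay within the 4.57 to 4.87 of the dendritic arrays. Without macrophage replicate 1 the lower members numbered 27, as they did without replicate 1 of both populations, a setting chosen after seeing the data. They numbered 4 without dendritic replicate 2 or macrophage replicate 2, 6 without dendritic replicate 3 and 3 without macrophage replicate 3. They numbered 20 with the replicate number as a block. Ccnb2 lost its call without dendritic replicate 2 (adjusted p = 0.0626) and without macrophage replicate 3 (0.0585), within a range of 1.57e-05 to 0.0626 over the alternatives. The list was called (camera adjusted p = 9.78e-08), but not with an estimated correlation (adjusted p = 0.414) nor by fry (adjusted p = 0.106). Genes of S phase went both ways and were not called as a list (camera adjusted p = 0.299). Of 25, 5 were higher and 4 lower (9 and 4 when adjusted over the list alone), with 1 lower without dendritic replicate 2 or macrophage replicate 2. The helicase subunit Mcm6 (1.54 ± 0.24) and thymidine kinase Tk1 (1.39 ± 0.20) were higher, and E2f1 (-1.05 ± 0.16) and Rrm2 (-1.14 ± 0.32, adjusted p = 0.0319) were lower. A second probe set of Tk1 gave 0.59 and was not called (adjusted p = 0.0957 among all probe sets). Rrm2 lost its call without dendritic replicates 1 or 2 or macrophage replicates 2 or 3, each left out singly (0.00198 to 0.111 over the alternatives).

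**Figure D3:**
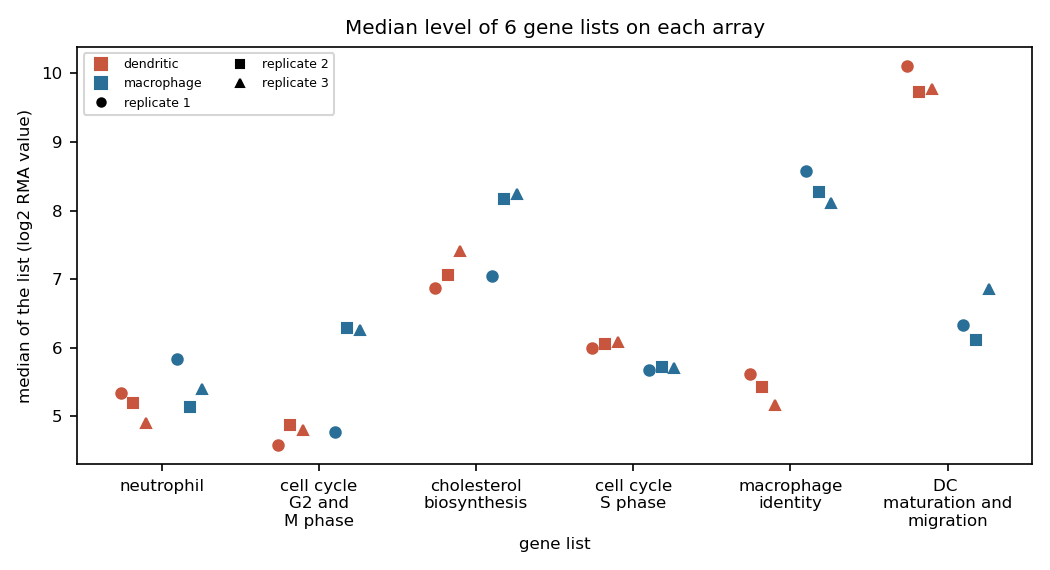
Median log2 RMA value (vertical axis) of the members of 6 gene lists (horizontal axis) on each array, with dendritic arrays in red, macrophage arrays in blue and the marker shape giving the replicate number. Macrophage replicate 1 (blue circle) lies at 4.77 for G2 and M phase and at 7.05 for cholesterol biosynthesis, away from the other macrophage arrays, whereas for the macrophage identity and DC maturation lists the populations are apart on all arrays.

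Cytokine genes were split. Of 24 inflammatory cytokine and chemokine genes 9 were lower and 3 higher (11 and 3 when adjusted over the list alone). Il12b and Il6 (3.75 ± 0.26) were higher in the dendritic population, and the chemokine Ccl3 (-3.67 ± 0.26) and Il1b (-3.37 ± 0.31) were lower. This list was called (camera adjusted p = 0.0226), but not without dendritic replicate 1 (adjusted p = 0.0725) nor with an estimated correlation (adjusted p = 0.274), within a range of 0.00464 to 0.274 over the alternatives. Genes of the type I interferon response were not called as a list (camera adjusted p = 0.575), with a median of -0.31 and a mean of 0.09. Of 26, 6 were higher and 3 lower (6 and 5 when adjusted over the list alone; 5 lower with the replicate number as a block), Mx1 (2.85 ± 0.51) and Bst2 (1.89 ± 0.20) being highest and Ddx58 (-1.71 ± 0.15) and Oas1a (-1.15 ± 0.19) lowest. Of 19 genes associated with alternative activation 10 were lower and 2 higher (11 and 2 when adjusted over the list alone), the lower including Mgl2 and Tgfbi and the higher being the decoy receptor Il1r2 (2.59 ± 0.48) and Il4ra (1.10 ± 0.16). The list call (camera adjusted p = 1.19e-05) was lost with an estimated correlation (adjusted p = 0.0611).

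Among growth factor and chemokine receptors of myeloid cells 9 of 21 were lower and 3 higher (12 and 4 when adjusted over the list alone; 5 higher with the replicate number as a block). Ccr2 and Csf1r were the lowest, and Flt3 and Kit (2.77 ± 0.45), the receptors of the early growth factors FLT3 ligand and stem cell factor, the highest. This call (camera adjusted p = 0.00554) was lost with an estimated correlation (adjusted p = 0.323). Of 25 integrin and adhesion genes 10 were lower and 4 higher (11 and 7 when adjusted over the list alone), with Itgam and Adgre1 lowest and Itga4 (2.19 ± 0.35) and Icam1 (1.48 ± 0.14) highest. The adhesion list was called (camera adjusted p = 0.0175), but not without dendritic replicate 2 (adjusted p = 0.0569) nor with an estimated correlation (adjusted p = 0.186), within a range of 0.00647 to 0.225 over the alternatives.

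Markers of the dendritic subsets were mixed. Of 20 genes of conventional DC type 1, 5 were higher and 5 lower (6 and 7 when adjusted over the list alone), with Ly75 (3.62 ± 0.20) and Cd8a (2.81 ± 0.13) highest, Naaa (-3.20 ± 0.24) and Rab7b (-2.77 ± 0.39) lowest, and no call (camera adjusted p = 0.887). The median of this list was 0.11 and its mean -0.05. Of 18 genes of conventional DC type 2, 6 were lower and 3 higher (10 and 4 when adjusted over the list alone; 10 and 5 with the replicate number as a block). Mgl2 and Clec10a (-4.64 ± 0.31), lectins that macrophages also carry, were the lowest, and the higher members included Ltb (1.26 ± 0.30) and Irf4. Only 1 member was higher without dendritic replicate 2, dendritic replicate 3 or macrophage replicate 2. Ltb lost its call without dendritic replicate 2 or macrophage replicate 2 (0.000566 to 0.0611 over the alternatives). The type 2 list was called as lower (camera adjusted p = 0.0177), but not without dendritic replicate 1 (adjusted p = 0.0531) nor with an estimated correlation (adjusted p = 0.309), within a range of 0.00148 to 0.309 over the alternatives. Of 13 plasmacytoid DC genes 4 were higher, led by Spib and Bst2, and 1 was lower, Lair1 (-2.51 ± 0.17), with the same counts when adjusted over the list alone. That list was not called (camera adjusted p = 0.0996), but it was without dendritic replicate 3 (adjusted p = 0.0378; 0.0378 to 0.286 over the alternatives), and 2 members were lower without macrophage replicate 1.

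Among monocyte genes 11 of 17 were lower and none was higher (12 lower when adjusted over the list alone), with Ccr2 and Mgst1 (-4.78 ± 0.33) lowest. The call (camera adjusted p = 1.34e-06) was lost with an estimated correlation (adjusted p = 0.102). In macrophage replicate 1 the median of this list was 8.17, against 6.48 and 6.90 on the other macrophage arrays and 4.95 to 5.55 on the dendritic arrays. Without that array the median difference of the list was -1.59 in place of -2.18, and 12 members were lower. Of 18 alveolar macrophage genes 6 were lower, Atp6v0d2 and Itgax among them, and 1 was higher, as also when adjusted over the list alone (camera adjusted p = 0.00330, and 0.162 with an estimated correlation). The higher member, Fabp1 (0.60 ± 0.17, adjusted p = 0.0369), lost its call without dendritic replicate 2, dendritic replicate 3 or any 1 macrophage array (0.00413 to 0.134 over the alternatives), and 2 members were higher with the replicate number as a block. Of 15 osteoclast genes 7 were lower, among them Atp6v0d2 and Acp5 (-3.53 ± 0.23), and 2 were higher, Car2 (2.99 ± 0.15) and the RANK receptor Tnfrsf11a (1.97 ± 0.14); when adjusted over the list alone these counts were 7 and 3. The osteoclast call (camera adjusted p = 0.0322) was lost without dendritic replicate 3 (adjusted p = 0.0589), without macrophage replicate 1 (0.0527), with genes under the 30th percentile of level left out (0.0741) and with an estimated correlation (adjusted p = 0.323), within a range of 0.0139 to 0.323 over the alternatives. Of 17 stem and progenitor genes 6 were higher, led by Flt3 and Kit, and 1 was lower (8 and 1 when adjusted over the list alone). The progenitor call (camera adjusted p = 0.00845) was lost with an estimated correlation (adjusted p = 0.266). The lower member Ikzf2 (-0.55 ± 0.13, adjusted p = 0.0175) lost its call without dendritic replicate 3, macrophage replicate 2 or macrophage replicate 3 (0.00226 to 0.0776 over the alternatives). With 75th percentile centring Ikzf2 was not called either (limma adjusted p = 0.0522).

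Markers of other blood and stromal cells were not called as lists. Of 23 neutrophil genes none was higher and 4 were lower, as also when adjusted over the list alone, with Mmp8 and the leukotriene receptor Ltb4r1 (-3.66 ± 0.22) lowest (camera adjusted p = 0.153; 0.0248 without dendritic replicate 1 and 0.0125 without macrophage replicate 2, within 0.0125 to 0.928 over the alternatives). In a contrast chosen after seeing the data, the neutrophil list was higher on the replicate 1 array of both populations, by a median of 0.57 in the dendritic and 0.43 in the macrophage arrays (camera adjusted p = 1.05e-08, and 0.366 with an estimated correlation). In the other lists the counts were the same when adjusted over the list alone. Of 16 B cell genes 2 were higher, Cd79a (0.81 ± 0.19) and Igll1 (0.53 ± 0.15, adjusted p = 0.0355), and 2 lower, Cd22 (-1.47 ± 0.12) and Cd37 (-0.74 ± 0.18), with a camera adjusted p of 0.884, a median of 0.11 and a mean of -0.05. Cd79a lost its call without dendritic replicate 2 or macrophage replicate 2 (0.000894 to 0.0545 over the alternatives), Igll1 without any 1 array except dendritic replicate 3 (0.0118 to 0.142) and Cd37 without macrophage replicate 3 (0.00602 to 0.0614). Igll1 was not called with median centring either (limma adjusted p = 0.0621). Of 20 T and NK cell genes the receptor Klrk1 (3.50 ± 0.24) was higher and none was lower, with 1 lower without dendritic replicate 1 (camera adjusted p = 0.285). Of 19 mast cell and basophil genes Kit was higher, and Hgf (-1.54 ± 0.37, adjusted p = 0.0151) and Cd200r3 (-0.91 ± 0.17) were lower (camera adjusted p = 0.553). With the replicate number as a block, and without dendritic replicate 2, 2 members were higher. Hgf lost its call without dendritic replicate 2 (0.00102 to 0.0542 over the alternatives). Of 14 erythroid and megakaryocyte genes Car2 was higher and 4 were lower, including the platelet chemokines Pf4 and Ppbp (-3.28 ± 0.45), with a camera adjusted p of 0.299, a median of 0.01 and a mean of -0.61. Of 11 eosinophil genes Ear6 (-1.11 ± 0.23) was lower (camera adjusted p = 0.306), and of 21 stromal and endothelial genes 3 were lower, with Cav1 (-3.70 ± 0.23) and Lepr (-2.58 ± 0.21) lowest (camera adjusted p = 0.169).

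**Figure D4:**
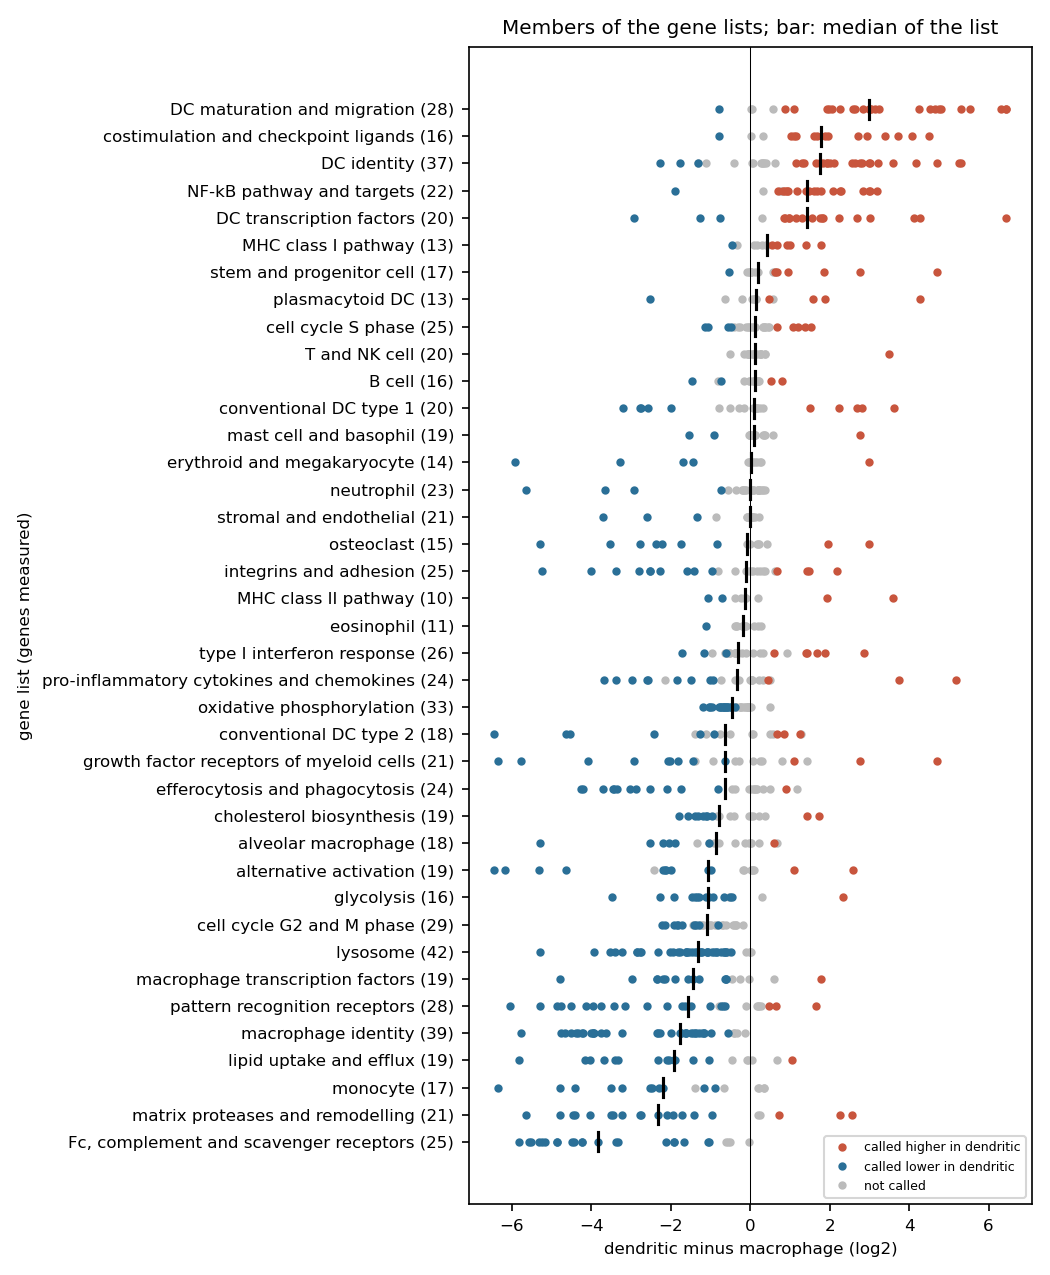
Log2 difference, dendritic minus macrophage (horizontal axis), of each measured member of the 39 gene lists (vertical axis, number of genes measured in brackets), with members called higher in red, called lower in blue and not called in grey, and the median of each list as a black bar. The medians run from 2.999 for DC maturation and migration to -3.82 for Fc, complement and scavenger receptors.

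Of the 39 lists, 27 were called by camera with a preset correlation of 0.01, 7 as higher and 20 as lower in the dendritic population. With a correlation estimated from the residuals 7 calls held, those of costimulation, DC maturation, DC transcription factors, Fc, complement and scavenger receptors, lysosome, macrophage identity and macrophage transcription factors. Their camera adjusted p lay between 0.0317 and 0.0356. Since this version tests on the 4 residual degrees of freedom, a lost call does not show that inter-gene correlation alone is the reason. Camera on ranks lost the calls of conventional DC type 2, growth factor receptors, integrins and adhesion, osteoclast and inflammatory cytokine genes. By fry, which does not set a list against other genes, G2 and M phase (adjusted p = 0.106), cholesterol biosynthesis (0.197) and inflammatory cytokine genes (0.0881) were not called. All other lists called by camera were also called by fry, and the plasmacytoid DC list was called by fry only (adjusted p = 0.00502). The lists overlap, so their tests are not independent.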

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

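The 4 main results (both gene counts and the DC and macrophage identity lists) kept their direction and their side of the threshold in all alternatives run, with 2 exceptions. The count of genes at least 2-fold apart, 2051, became 838 with treat against a log2 difference of 1, which by construction asks more of each gene. The DC identity list had an adjusted p of 0.0622 with an estimated inter-gene correlation, against 3.75e-12 to 9.07e-07 in its other alternatives. The count of called genes, 4312, ranged from 2902 at an adjusted p under 0.01 to 5901 with array weights, and from 3311 to 4625 with each array left out. The 2-fold count lay between 1864 (dim genes left out) and 2139 (array weights) apart from treat. It ranged from 1982 to 2109, the DC identity p from 3.75e-12 to 3.40e-09 and the macrophage identity p from 1.23e-34 to 2.58e-29 with each array left out. Without replicate 1 of both populations, chosen after seeing the data, the counts were 4921 and 2120 and the p values 3.80e-09 and 8.15e-28. With the replicate block the counts were 5207, of which 4304 were called the same way without it, and 2082, and the p values 3.30e-09 and 3.97e-29. Cx3cr1 was the only named gene whose call changed with the block, and no list call did. Of 122 called genes named, 106 were called in every alternative that tested them. The medians of 2 called lists turned positive. That of integrins and adhesion, -0.12, was 0.046 with array weights and 0.055 without replicate 1 of both populations, and reached -0.430 without macrophage replicate 2. That of osteoclast genes, -0.09, was 0.030 without dendritic replicate 3 and 0.028 without macrophage replicate 2, and reached -0.351 without dendritic replicate 2. The cause was not tested. No scaling moved the median difference of all genes beyond 0.089, and the share of calls that were higher, 46.2%, lay between 44.4% and 50.8% under the scalings. Signal over background limits dim genes, for which no detection calls exist.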

Other observations

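The gene families in this and the next paragraph, the test within replicate numbers, the test of dilution and the replicate 1 contrast were chosen after the values were seen. Families were taken by symbol and tested like the lists. Of 33 C-type lectin genes with a Clec symbol, 15 were lower and 3 higher in the dendritic population (camera adjusted p = 2.15e-05, and 0.156 with an estimated correlation). C-type lectins with other symbols, such as Mgl2, were not counted here. The lower genes included Clec4a1 (-5.59 ± 0.22), Clec4a3 (-5.44 ± 0.13) and Clec4e (-4.86 ± 0.16), and the highest of the 33 was Clec2i (1.77 ± 0.14). Clec9a, a receptor of conventional DC type 1, was lower by this measure (-2.57 ± 0.16). Of 8 Cd300 receptor genes 6 were lower, led by Cd300c2 (-4.74 ± 0.17), and none was higher (adjusted p = 2.14e-06, and 0.158 with an estimated correlation). Of 9 genes of the Klk1 kallikrein family 6 were lower (adjusted p = 2.15e-05, and 0.230 with an estimated correlation), but these genes are near-identical and their probe sets cannot be taken as independent. Of 24 vacuolar ATPase genes 10 were lower (adjusted p = 0.000337, and 0.188 with an estimated correlation), of 9 Schlafen genes 5 were lower (adjusted p = 0.00586, and 0.188 with an estimated correlation), and of 9 P2Y receptors P2ry6 (-5.08 ± 0.19) and 3 others were lower and P2ry10 (3.01 ± 0.28) was higher (adjusted p = 0.00539, and 0.158 with an estimated correlation). The medians of these 6 families stayed negative under all 3 other scalings, where the higher C-type lectin genes numbered 2 to 4, the lower P2Y receptors 4 to 5, the lower Schlafen genes 4 to 5 and the higher vacuolar ATPase genes at most 1.

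Several families had large members in both directions and were not called. Among 22 matrix metalloproteinases Mmp25 (5.12 ± 0.16) and Mmp23 (2.26 ± 0.15) were higher and 6 were lower (camera adjusted p = 0.283). Among 20 semaphorins Sema7a (4.97 ± 0.19) was the highest and Sema4b (-2.17 ± 0.22) the lowest (adjusted p = 0.411). Among 19 tetraspanins Tspan13 (3.71 ± 0.14) and Tspan33 (2.01 ± 0.12) were higher and Tspan32 (-2.68 ± 0.16) lower (adjusted p = 0.494). Among 8 guanylate-binding protein genes 4 were higher, led by Gbp5 (2.14 ± 0.26), while Gbp7 was lower (-3.55 ± 0.31; adjusted p = 0.283). Of 19 Ms4a genes 5 were lower, led by Ms4a6d (-4.52 ± 0.32; adjusted p = 0.145). Of 24 Serpinb genes 3 were higher and 2 lower (adjusted p = 0.283), against 6 and 2 with arrays centred on their 75th percentiles and 4 and 3 after quantile normalization was applied again. Of 6 Siglec genes 1 was higher (adjusted p = 0.673). Of 57 cytosolic ribosomal protein genes 2 were higher and none was lower (adjusted p = 0.145). With the replicate number as a block more members of these and the preceding families were called, and no family call changed. Serpinb1a (limma adjusted p = 0.0206), Serpinb1b (0.0362), Serpinb6a (0.0442) and the Schlafen gene Slfn5 (0.0263) were then higher. Ms4a8a (0.0214) and Ms4a4c (0.0271) were then lower.

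DC maturation and NF-kB genes were higher in the dendritic population although the labels call both populations unstimulated. Handling or sorting stress of the dendritic samples would raise immediate early and heat shock genes, a list written before its test. The median difference of its 22 measured genes was 0.024 (SD of members 0.69), below the maturation median of 2.999 by more than that spread. Of these genes 6 were higher, such as Ier5 (1.26 ± 0.14), and 2 lower (5 to 6 and 0 to 2 under the other scalings). The median argues against stress confined to the dendritic samples as the cause of the whole pattern. Stress shared by both populations would largely cancel in this difference, so the test cannot address it. The lowest median of the maturation list within a replicate number was 2.78, so no single numbered pair of arrays carried the difference. The labels do not say whether the numbers mark separate preparations, so this cannot decide whether a single preparation is its source. Also open is maturation of the dendritic population in culture, or a separation of the populations by markers that rise with maturation, and neither was tested.

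The replicate 1 arrays of both populations deviated together, and 47 genes differed between them and the other arrays (32 higher, 15 lower; limma, adjusted p under 0.05). Retnlg, a member of the neutrophil list, was at 7.43 and 7.39 on the replicate 1 arrays and at 4.25 to 4.33 on the others. Plet1 was at 6.40 and 7.26 against 9.17 to 10.99. The neutrophil list members Camp (1.62, limma adjusted p = 0.0306) and Ltf (1.62, 0.0440) were also called higher. Its members Cxcr2 (1.75, 0.0575) and Lcn2 (1.39, 0.0598) did not pass. Remaining differences between the distributions of the arrays are argued against, since the deviations still correlated at 0.343 after quantile normalization was applied again. RMA already includes that step, so this cannot decide on array effects that the step leaves in place. In this contrast 17 of the 39 lists were called by camera (13 higher, 4 lower), and none with an estimated correlation. The lowest p was that of G2 and M phase (lower, adjusted p = 3.74e-10, and 0.553 with an estimated correlation), and cholesterol biosynthesis (lower, 7.88e-06, and 0.558) and glycolysis (higher, 0.000692, and 0.501) were among the others. The median deviation of G2 and M phase was -1.37 in macrophage replicate 1 but -0.24 in dendritic replicate 1. For cholesterol biosynthesis these values were -1.14 and -0.24, and for glycolysis 0.21 and 0.42. The first 2 lists thus fell mainly in macrophage replicate 1. RNA of neutrophils was tested as a source: the 23 neutrophil genes were higher by a median of at least 0.426 in both populations (adjusted p = 1.05e-08, and 0.366 with an estimated correlation). This size lies between those set in advance for and against it, so the source stays open, and many lists other than that of neutrophils moved. Dilution by neutrophil RNA may not account for the lower mitotic genes of macrophage replicate 1 (median deviation -1.37), since the macrophage identity list there deviated by 0.301 (SD of members 0.41) in the other direction, and no biological explanation was tested.

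Oxidative phosphorylation genes were lower in the dendritic population by a median of -0.45. An intensity-dependent shift of the arrays is argued against by random lists matched on mean level, whose medians centred on 0.03. Of 10000 such lists 0 had a median as low, and with 1 added to both numbers the share is 0.01%. A single outlying array is argued against by the median with each array left out, which was at most -0.411. The ribosomal protein median was 0.096. A lower expression of these genes in the dendritic population is a hypothesis found and tested on the same data, and the list call was lost with an estimated correlation (adjusted p = 0.309).

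The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Each other split mixes the populations, which puts their difference into the residual spread. Its low counts thus follow from the design and give no measure of chance. For the number of called genes 1 of the 10 splits, the real one, reached 4312, and the highest other gave 0. For genes at least 2-fold apart 1 split reached 2051, and the highest other gave 0. For the DC identity list 1 split reached a camera -log10 p of 10.8, the highest other giving 4.34, and for the macrophage identity list 1 split reached 32.3, the highest other giving 9.37. Of the other splits, 3 part all 3 same-numbered pairs as the real one does, with 0 genes and at most 3.83 and 9.33 for these lists, and 6 part a single pair.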
